A study of Mus musculus with 2 samples.

How the data were processed

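H3K4me3, a methylated form of histone H3 known to sit at gene start sites, was measured by chromatin immunoprecipitation and sequencing in neural tube from mouse embryos of the strain B6NCrl at embryonic day 11.5. Per the labels, there were 2 biological replicates, pools of 109 embryos (replicate 1) and 88 embryos (replicate 2) of both sexes, and the size range recorded for the libraries was 300 to 500, taken here as bp. Both replicates belong to 1 group, so no condition, stage or tissue was compared, and group and replicate number were taken from the labels.

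The authors deposited 4 peak lists in mm10 coordinates. Per the descriptions deposited with the files, 1 list came from the filtered alignments of each replicate, a pooled list came from the alignments of both, and a replicated list was derived from the other 3. The lists of the replicates, and the pooled list, also drew on further files, 1 of which they shared. The peak caller, its version, the aligner and the rule that made the replicated list are not given in the sources used here. All 20804 replicated peaks were identical to rows of the pooled list, so the replicated list carries the pooled positions and values. The deposited signal value of a peak is the authors' own number for that peak, is not scaled between lists, and was used to describe, rank or filter peaks within a list and for the correlation between replicates. The deposited -log10 q of a peak was used only for a stricter list with a minimum of 5. The lists also hold peaks of low -log10 q, down to 0.149 in the replicated list. Under 5 lay 11.4% of replicated peaks, 27.8% of those of replicate 1 and 36.9% of those of replicate 2. The deposited start and end of each peak, with its summit, are positions and carry no normalization. The files hold no read counts, so the sequencing depth of each replicate is unknown, and no counting interval was computed. Peak calling on unequal depth would give unequal lists, which the files cannot separate from other differences. An input or control track was not used here, and signal tracks were not analysed here.

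The reference was the mouse genome GRCm38.p6, the build that mm10 names, with the GENCODE M21 annotation (Ensembl 96). Promoters were start sites of the GENCODE basic transcripts of 21938 protein-coding genes on chromosomes 1 to 19, X and Y, with a window of 1 kb on each side. A gene was called marked when a peak of the replicated list overlapped that window at 1 or more of its start sites. Peaks on unplaced or unlocalized scaffolds, 11 of the replicated list, were left out of everything that needs the annotation. Domains were made by merging peaks across gaps of at most 1 kb, and a promoter domain is a domain that overlaps a promoter window. Peaks away from promoters were counted against start sites of all gene types and all transcripts, at distances over 1 kb and over 5 kb. The CpG content of a start site was the observed over expected CpG ratio of the sequence within 500 bp on each side.

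Overlap between the replicates' lists needed at least 1 bp, and its chance level came from 100 seeded random placements of the peaks on their own chromosomes. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests. Domain widths were compared by two-sided permutation tests of the median log2 width with 100000 resamples, for lists with at least 8 domains. Benjamini-Hochberg adjustment ran over the 21 lists tested for coverage and the 18 tested for width, with a threshold of 0.05. The 20 gene lists, the olfactory receptor family as a further list, the tests, most alternatives and the rule for named genes were fixed before the data were examined. Some genes stand on more than 1 list (Isl1, Sox10, Foxd3 and Ptf1a among them). Genes are not independent replicates, and neighbouring genes can share a domain, so these tests compare lists of genes and not animals.

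Genes were named by rule. For each list these were up to 4 marked members in the widest domains and up to 4 unmarked members in list order, or all of them where at most 8 were unmarked. Further names came from the 20 widest promoter domains, with the gene nearest the midpoint of each, and the 10 highest signal values at a start site. The rule also took the 5 highest peaks of each replicate that overlapped no peak of the other, and the 5 widest domains over 5 kb from any start site. Olfr658 and Olfr94, the marked olfactory receptor genes, further marked members of the somite and endothelial lists, and the genes in the closing observations, were chosen after their values were seen. Values with an SD are the mean of the replicates' own lists.

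The tests were checked on simulated marks and widths. The simulations marked genes independently and gave each gene its own domain. They therefore do not cover genes that share domains or marking that follows CpG content. For coverage, simulated over the 21938 genes, 2 of 2 lists changed by construction were called, and 1 of 19 unchanged lists was called. For width, simulated over 12022 domains, the 1 changed list was called with a log2 difference of 0.99 against 1 set, and 0 of 20 unchanged lists were called. Alternatives changed 1 choice at a time: the overlap rule, the window, the merging gap, the list of peaks, stricter subsets by -log10 q or signal value, the background genes, CpG-matched random lists (10000), and each replicate's list alone. For the CpG-matched lists, the smallest adjusted p that full marking could give was computed after the data were seen. Widths matched on CpG or signal and start sites of all GENCODE transcripts were added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and samtools 1.23.1, with the random seed 11.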

Results

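H3K4me3 peaks were mapped in neural tube of mouse embryos at embryonic day 11.5, a stage at which spinal cord progenitors are patterned and give rise to neurons. The 2 biological replicates were pools of 109 and 88 embryos. The list of replicate 1 held 25312 peaks with a median width of 1013 bp, covering 31.7 Mb, and that of replicate 2 held 27773 peaks with a median width of 815 bp, covering 30.7 Mb. The list called on both replicates together held 23545 peaks, and 20804 of these formed the replicated list, with a median width of 1348 bp and 31.6 Mb covered, or 1.16% of the chromosomes. Of these 20804 peaks, 19542 overlapped a peak in both replicates' own lists, so a replicated peak was not always found in each. The 2741 pooled peaks left out of the replicated list were weak, with a median signal value of 3.13 against 20.7 for the replicated peaks. Sequencing depth is unknown from these lists.

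The first question was how far the 2 embryo pools gave the same marked regions. Peaks of replicate 1 overlapped a peak of replicate 2 in 82.3% of cases (20828 of 25312), and peaks of replicate 2 overlapped replicate 1 in 79.8% (22162 of 27773). Random placement gave means of 2.68% and 2.44%, with maxima of 2.94% and 2.64% over 100 placements. Shared peaks held 95.98% of the bp of replicate 1 and 95.3% of those of replicate 2. The 4484 peaks found in replicate 1 alone had a median width of 251 bp and a median signal value of 3.51, against 1288 bp and 19.4 for its shared peaks. The 5611 peaks found in replicate 2 alone had 228 bp and 3.18, against 1151 bp and 15.5. The highest peaks without a partner in replicate 1 reached signal values of 7.89 (chromosome 2, 128892274 to 128892726, 28342 bp from Fbln7), 7.75 (chromosome 7, 43283000 to 43283322, nearest Zfp715), 7.39 (nearest Ccnd2, a D-type cyclin, at 115220 bp), 7.39 (nearest Hmga2) and 7.24 (nearest Map3k11). In replicate 2 they reached 6.75 (chromosome X, 60147352 to 60147761, at a start site of Mcf2), 6.35 (nearest Impa2), 6.34 (nearest Gm26558), 6.23 (nearest Arhgef16) and 6.15 (nearest Dchs2). Across the 19542 replicated peaks present in both lists, signal values of the replicates had a Spearman's rho of 0.947 and a Pearson's r of 0.947 on the log2 scale. The correlation is across peaks, which are not independent replicates.

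Peaks lay mostly at the start sites of protein-coding genes. Of the 20793 replicated peaks on chromosomes, 14069 (67.7%) were within 1 kb of such a start site, against a mean of 3.66% and a maximum of 3.88% for random placements. These promoter peaks held 83.6% of the bp covered. They were wider (median 1701 bp against 576 bp) and had higher signal values (31.4 against 5.34) than the rest. With start sites of all gene types, 77.5% of replicated peaks were at a start site. In the lists of the single replicates the share at protein-coding promoters was 59.3% and 56.0%. Among the stronger 50% of replicated peaks by signal value it was 94.7%.

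By gene, 13996 of 21938 protein-coding genes (63.8%) were marked, and the replicates' own lists marked 64.3% ± 0.119 (SD, n = 2). Of all 21938 genes, 13950 were marked in the lists of both replicates, 136 in that of replicate 1 only and 173 in that of replicate 2 only, whether or not the replicated list marked them. Among other gene types, 33.9% of antisense genes, 12.9% of lincRNA genes and 1.28% of processed pseudogenes had a peak at a start site. In the replicated list the highest signal values at a start site belonged to Msl1 (82.4), which encodes a subunit of a histone acetyltransferase complex, Dnajc11 (80.0), Alyref (79.5), an mRNA export factor, the splicing factor gene Sfpq (79.4), and Arid1a (78.8), a subunit of SWI/SNF chromatin remodellers. They were followed by the lamin gene Lmnb1 (78.6), the chaperone gene Hsp90ab1 (76.6), Msi1 (76.6), which encodes an RNA-binding protein of neural progenitors, the translation factor gene Eif3b (76.2) and Mex3c (76.1). The order differed in the list of replicate 2, where Mex3c had 65.0 and Msl1 58.2.

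The neural progenitor, spinal neuron, pan-neuronal and Hox lists were fully marked in the replicated list. All 20 neural progenitor genes (adjusted exact p = 3.89e-04), all 38 transcription factors of spinal neuron subtypes (adjusted exact p = 2.63e-07), all 25 pan-neuronal genes (adjusted exact p = 5.28e-05) and all 39 Hox genes (adjusted exact p = 2.06e-07) had a marked promoter, in each replicate as in the replicated list. Other protein-coding genes were marked in 63.8% of cases by comparison. Of 30 factors of dorsoventral progenitor domains, 29 were marked (adjusted exact p = 6.76e-05). The exception was Arx, which had a peak in replicate 1 only. The patterning signals of the Shh, Bmp, Wnt, Fgf and retinoid pathways were marked in 36 of 37 cases (adjusted exact p = 6.68e-06), with Cyp26c1, a retinoic acid hydroxylase gene, unmarked. Genes of the mature synapse and of transmitter synthesis were marked in 23 of 25 cases (adjusted exact p = 0.00435), including Slc32a1, Slc17a6, Slc6a5 and Chat, genes of inhibitory, glutamatergic, glycinergic and cholinergic transmission. The unmarked members were Th and Tph2, rate-limiting enzymes of catecholamine and serotonin synthesis. Neural crest and sensory ganglion genes were marked in 22 of 24 cases (adjusted exact p = 0.00670), with Dct unmarked and Phox2b marked in replicate 2 only. All p-values are from two-sided Fisher's exact tests adjusted over the 21 lists. Several calls were not kept among the stronger 50% of replicated peaks, which marked 49.3% of all genes. The spinal neuron list was then at 26.3% (adjusted exact p = 0.00783) and the synapse list at 20% (adjusted exact p = 0.00670), both below other genes. The dorsoventral list was at 36.7% (adjusted exact p = 0.249), the patterning list at 48.6% (1.00), the pan-neuronal list at 60% (0.374) and the neural crest list at 54.2% (0.759), and none of these passed. The neural progenitor (90%, adjusted exact p = 4.31e-04) and Hox calls (69.2%, adjusted exact p = 0.0215) held. The Hox p-values take the 39 genes as separate, although these lie in 18 domains, and coverage was not tested by domain.

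**Figure D1:**
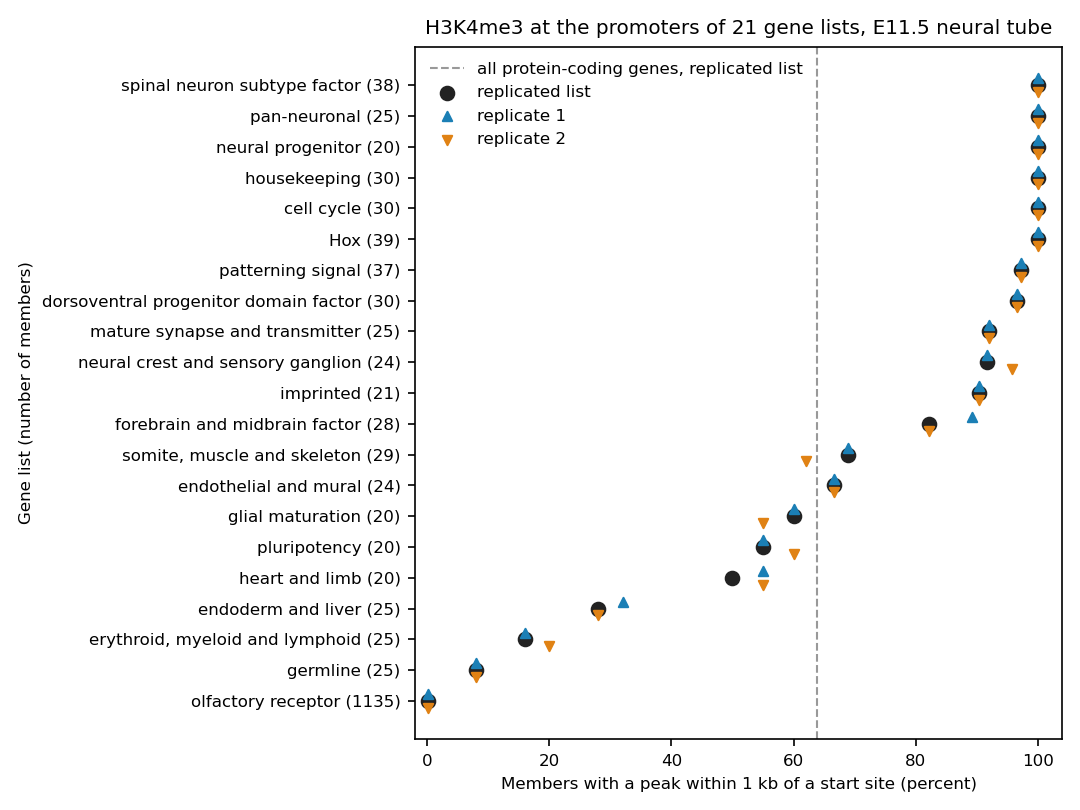
The horizontal axis is the percent of list members with a peak within 1 kb of a start site and the vertical axis lists the 21 gene lists with their numbers of members; circles are the replicated list, triangles the lists of each replicate, and the dashed line is the 63.8% of all protein-coding genes. The neural progenitor, spinal neuron, pan-neuronal, Hox, cell cycle and housekeeping lists sit at 100% and the olfactory receptors at 0.176%.

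Olfactory receptor, germline, blood, and endoderm and liver genes were marked less often than other genes. Olfactory receptor genes were marked in 2 of 1135 cases (0.176%, with a p below the range of floating-point numbers), namely Olfr658 and Olfr94. Germline genes were marked in 2 of 25 cases (adjusted exact p = 9.36e-08), the meiotic recombinase gene Dmc1 and Dazl, while Ddx4, Sycp1, Sycp2 and Sycp3 were unmarked. Of 25 blood genes 4 were marked (adjusted exact p = 5.22e-06): the erythroid transcription factor genes Klf1 and Nfe2, the erythropoietin receptor gene Epor and the glycophorin gene Gypa. The globin genes Hba-a1, Hba-x, Hbb-y and Hbb-bh1 had no peak in any list. Endoderm and liver genes were marked in 7 of 25 cases (adjusted exact p = 8.60e-04), among them Foxa1, Foxa3, Hnf1b and Ptf1a, the last also a dorsal spinal cord factor. Alb, Afp, Ttr and Apoa1, which encode plasma proteins, were unmarked.

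The somite, muscle and skeleton list (20 of 29, adjusted exact p = 0.773) included marked Foxc1, Foxc2, Meox1 and Col2a1 and unmarked Myf6, Myog, Actc1 and Acta1. Also marked were Col1a1, Meox2, Myf5, Myod1, Sp7, Tbx6 and Tnnt1, of which Myf5 and Tnnt1 were not marked in the list of replicate 2. The endothelial and mural list (16 of 24, adjusted exact p = 0.835) included marked Prox1, Foxf2, Egfl7 and Pdgfrb, whereas Pecam1, Tek, Tie1, Emcn, Robo4, Rgs5, Acta2 and Lyve1 were unmarked. Its members Cd34, Cdh5, Cldn5, Cspg4, Eng, Erg and Esam were marked too. In the heart and limb list (10 of 20, adjusted exact p = 0.302) Isl1, Shox2, Gata6 and Mef2c were marked and Nkx2-5, Tbx5, Hand1 and Myh6 were not. The pluripotency list (11 of 20, adjusted exact p = 0.567) held marked Tbx3, Klf4, Sall4 and Lin28a. Its core members Pou5f1 and Nanog were unmarked, as was Zfp42, and Tdgf1 had a peak in replicate 2 only. The glial maturation list (12 of 20, adjusted exact p = 0.835; 55.6% in genes of the same CpG content) was divided between marked Pdgfra, Sox10, Slc1a2 and Slc1a3 and the unmarked Gfap, Aqp4, S100b, Plp1, Mog, Mag, Mobp and Opalin, most of them products of differentiated astrocytes and oligodendrocytes.

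Factors of forebrain and midbrain were marked in 23 of 28 cases (adjusted exact p = 0.0639), which did not pass the threshold. Bcl11b, Emx2, Satb2 and Dlx2 were marked. Rax and Neurod6 had no peak, Otx2 and Nkx2-1 had a peak in replicate 1 only, and Fezf2 in replicate 2 only. With the list of replicate 1 alone 25 members were marked, and the call then passed (adjusted exact p = 0.00681). All 30 cell cycle genes and all 30 housekeeping genes were marked (adjusted exact p = 6.68e-06 for each). Of 21 protein-coding imprinted genes 19 were marked (adjusted exact p = 0.0151), with Ndn and Rtl1 unmarked. The imprinted noncoding genes H19, Meg3, Kcnq1ot1 and Airn were marked in both replicates. Among the stronger 50% of peaks the imprinted call was lost (47.6%), and the forebrain (7.14%), somite (20.7%), endothelial (12.5%), heart and limb (10%) and pluripotency (5%) lists lay below other genes, with adjusted exact p-values of 1.11e-05, 0.00414, 5.96e-04, 7.82e-04 and 1.08e-04.

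The lists were also set against genes of the same CpG content. Random genes of the same CpG deciles would be marked in 71.1% of cases for the pan-neuronal list (adjusted permutation p = 0.00140), 89.7% for Hox (0.0483), 58.4% for germline (0.00140) and 5.21% for olfactory receptors (0.00140), and these calls held. The Hox value, close to the threshold, again takes genes that share domains as separate. The endoderm and liver call did not hold (matched share 44.1%, adjusted permutation p = 0.0739), nor did those of the synapse (77.5%, 0.0960), imprinted (85.3%, 0.807) and blood lists (14.9%, 1.00). For 7 lists the test could not show a higher share, since marking of every member would still miss the threshold. These were the neural progenitor (matched share 91.2%, adjusted permutation p = 0.155), dorsoventral (92.8%, 0.807), spinal neuron (93.4%, 0.0960), neural crest (89.9%, 1.00), patterning (91.5%, 0.263), cell cycle (97.4%, 0.977) and housekeeping lists (96.9%, 0.925).

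The width of the marked domain separated the lists further. Promoter domains, 13189 in all, had a median width of 1850 bp, and 414 of them (3.14%) spanned at least 5 kb. Neural progenitor genes lay in domains with a median of 6534 bp, 3.54-fold the median of other promoter domains (log2 difference 1.82). Spinal neuron factors had a median of 4251 bp (log2 difference 1.20), Hox genes 4609 bp over 18 domains (1.32), neural crest genes 3722 bp (1.01), patterning signals 3498 bp (0.92), pan-neuronal genes 3447 bp (0.90) and dorsoventral factors 3291 bp (0.83). Each of these 7 lists had an adjusted permutation p of 5.14e-05, from raw values of 2.00e-05, the smallest the resamples can give. The medians in each replicate's own list were also above 3 kb for all 7.

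The widest neural progenitor domains were those of Pax6 (14.7 kb in the replicated list; 15.2 ± 0.870 kb, mean and SD of the replicates' lists, n = 2), Zic1 (14.0 kb; 13.1 ± 1.34 kb), Zic2 (11.4 kb; 11.2 ± 0.397 kb) and Msi1 (10.6 kb; 11.3 ± 0.203 kb). Among dorsoventral factors they were Irx5 (13.1 kb), Pax3 (11.6 kb), Irx3 (9.62 kb) and Nkx6-1 (8.15 kb), although the last 2 measured 5.60 ± 0.0523 kb and 4.52 ± 0.0650 kb in the replicates' own lists. Among spinal neuron factors they were Lhx5 (16.6 kb; 16.6 ± 0.0382 kb) and Lhx1 (11.6 kb; 12.2 ± 0.745 kb), which are LIM homeodomain factors, with Foxd3 (9.20 kb) and Tlx3 (8.80 kb). In the pan-neuronal list Myt1, Elavl2, Crmp1 and Ina had domains of 6.73, 6.55, 6.54 and 6.35 kb. In the patterning list Rara (11.4 kb), Axin2 (9.19 kb), Ptch1 (7.58 kb) and Wnt7b (7.07 kb) led. The neural crest list was led by Tfap2a (13.5 kb), Foxd3, Twist1 (7.34 kb) and Prrx1 (6.64 kb).

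Smaller differences were found for imprinted genes (2999 bp, log2 difference 0.70, adjusted permutation p = 4.40e-04), with Gnas, Igf2, Mest and Peg3 widest, cell cycle genes (2860 bp, 0.63, adjusted permutation p = 1.35e-04), with Ccnd2, Ccnd1, Rrm2 and Cdk6 widest, and housekeeping genes (2538 bp, 0.46, adjusted permutation p = 0.00419), with Rpl13a, Rps18, Chmp2a and Eef2 widest. Somite, muscle and skeleton genes (2481 bp, 0.42, adjusted permutation p = 0.0267) and synapse genes (2434 bp, 0.40, adjusted permutation p = 0.0291) were also wider. Domains of glial maturation genes (1184 bp, log2 difference -0.64, adjusted permutation p = 0.0166) and of endoderm and liver genes (900 bp over 8 domains, -1.04, adjusted permutation p = 0.00349) were narrower. In the forebrain and midbrain list (1783 bp, adjusted permutation p = 0.818), the heart and limb list (1718 bp, 0.780), the endothelial list (1809 bp, 0.880) and the pluripotency list (2132 bp, 0.434) no difference passed the test.

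The permutation tests over domains were two-sided. Hox genes share long domains: with each gene counted once their log2 difference was 4.804, above the 1.75 of neural progenitor genes, and the synapse (0.33), glial (-0.47) and somite (0.34) calls were lost. Without merging across gaps the log2 difference of the spinal neuron list was -0.046 (adjusted permutation p = 0.722), that of the somite list -0.29 and that of the synapse list 0.016, while the forebrain (-0.80), heart and limb (-0.51) and endothelial (-1.17) lists passed as narrower. With gaps of 3 kb merged the spinal neuron difference was 2.04, the heart and limb (0.80) and pluripotency (0.93) lists passed as wider, and the Hox (0.46, adjusted permutation p = 0.0751), synapse (0.38) and glial (-0.44) calls were lost. The glial call was also lost in each replicate's own list (-0.32 and -0.40), and the endoderm (-0.18) and housekeeping (0.22) calls were lost after matching on signal value.

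**Figure D2:**
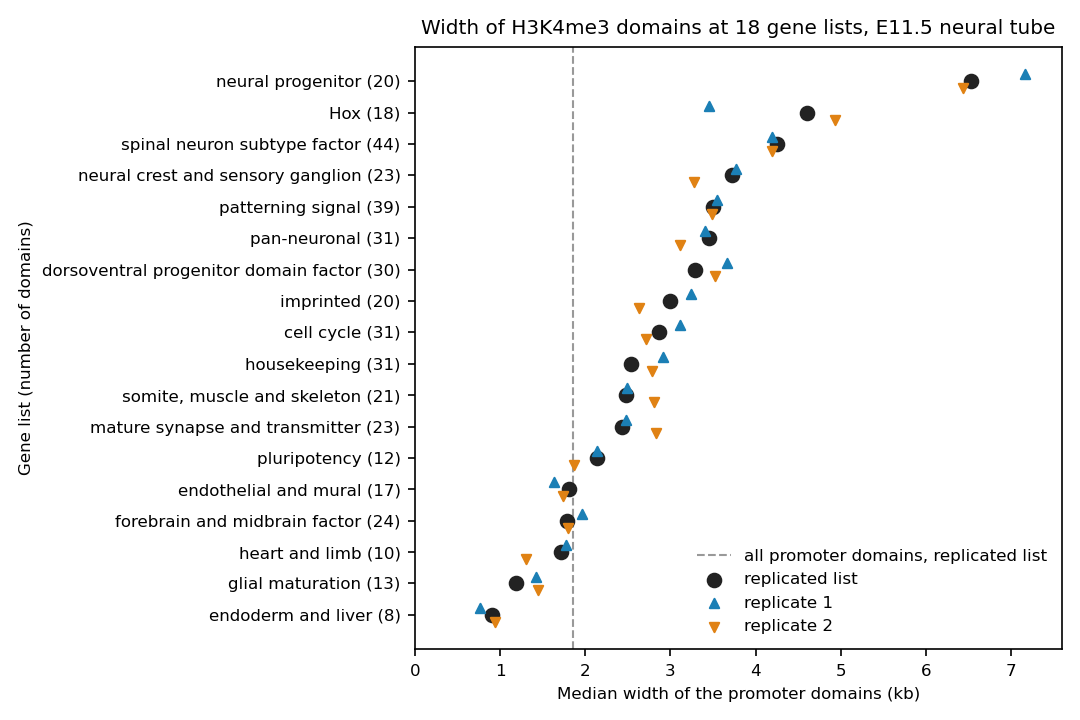
The horizontal axis is the median width of promoter domains in kb and the vertical axis lists the 18 gene lists with at least 8 domains and their numbers of domains; circles are the replicated list, triangles each replicate's own list, and the dashed line is the median of all promoter domains, 1850 bp. With each domain counted once, neural progenitor genes have the widest median in the replicated list, 6534 bp, and endoderm and liver genes the narrowest, 900 bp.

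The widest domains of the whole map covered the Hox clusters, which hold the homeobox genes that pattern the body axis. A domain of 88.3 kb on chromosome 11 (96267202 to 96355502, mm10) held Hoxb2 to Hoxb9, with Hoxb4 nearest its midpoint, and measured 90.2 ± 2.84 kb in the replicates' lists (n = 2). On chromosome 6 a domain of 62.3 kb (52187857 to 52250189) around Hoxa7 held Hoxa3 to Hoxa11, and a domain of 31.0 kb held Hoxa1 and Hoxa2. In replicate 2 these merged into 94.7 kb, whereas in replicate 1 the domain of Hoxa7 spanned 53.3 kb. Each gene is placed in the widest domain at any of its start sites. The outermost start site of Hoxa3 (52213115) lies beyond those of Hoxa4 to Hoxa6. On chromosome 15 domains of 54.1 kb around Hoxc5 and 28.7 kb around Hoxc9 held Hoxc4 to Hoxc10, and in replicate 2 these merged into 83194 bp. On chromosome 2 domains of 22.4 kb and 22.2 kb lay around Hoxd10 and Hoxd4, of which the former spanned 14619 bp in replicate 2 and the latter 37866 bp in replicate 1. Replicated peaks covered 86.0% of the Hoxa cluster (84.3% ± 0.519, SD, n = 2), 55.4% of Hoxb (55.0% ± 0.909), 72.6% of Hoxc (71.0% ± 0.443) and 66.1% of Hoxd (64.5% ± 3.13). Cluster limits were set by the outermost annotated Hox transcripts, so the long interval between Hoxb13 and Hoxb9 counts in the share of Hoxb.

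**Figure D3:**
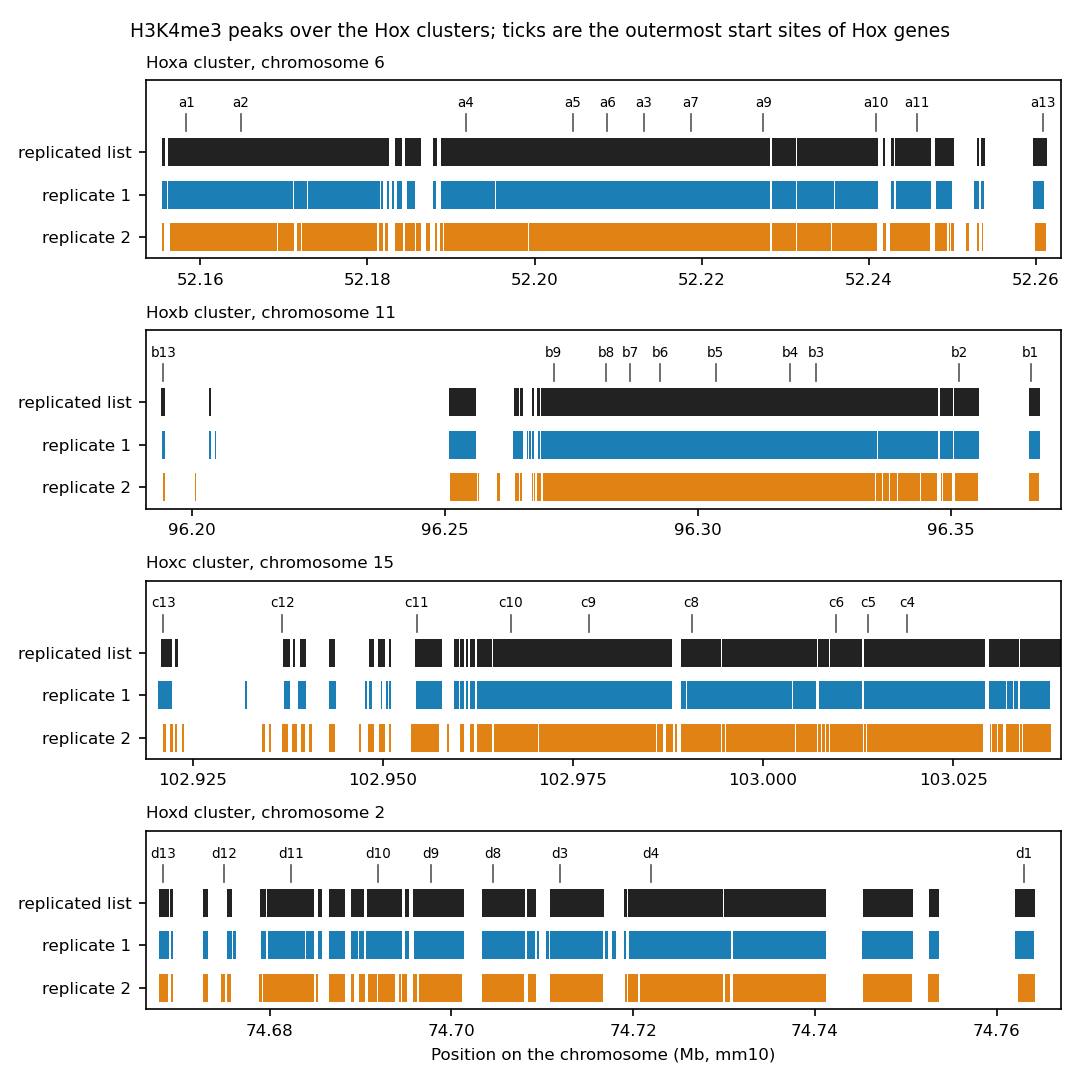
Each panel maps a Hox cluster in mm10 coordinates (Mb); bars are peaks of the replicated list (black), replicate 1 (blue) and replicate 2 (orange), and ticks mark the outermost annotated start site of each Hox gene, which for genes with distant alternative starts lies away from the main one. Peaks cover 86.0% of the Hoxa cluster, and the interval between Hoxb13 and Hoxb9 is largely free of peaks.

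Outside the Hox clusters the widest promoter domain of the replicated list was that of Nr2f2, although Pou3f3 was wider by the mean of the replicates' lists. Nr2f2 and Nr2f1, orphan nuclear receptor genes, had domains of 22.95 kb (18.3 ± 6.67 kb in the replicates' lists, n = 2, with 13545 bp in replicate 2) and 15.1 kb (13.5 ± 2.27 kb). The POU factor genes Pou3f3 and Pou3f2 had domains of 21.9 kb (21.7 ± 0.0870 kb) and 15.9 kb (15.8 ± 0.104 kb). The Hox cofactor genes Meis2 and Meis1 had 17.0 kb (17.1 ± 0.566 kb) and 14.3 kb (14.9 ± 0.780 kb). Lhx5, Tbx2 (15.7 kb; 12.9 ± 0.0834 kb), Pax6, Zic1 and Tfap2a (13.5 kb; 11.4 ± 2.93 kb) were also among the 20 widest. Midn (17.8 kb; 13.6 ± 1.04 kb) and Setd1b (13.3 kb; 13.3 ± 0.0658 kb), the latter encoding a histone H3K4 methyltransferase, were in this group too.

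Peaks away from any annotated start site were fewer and weaker. Of the 20793 replicated peaks, 4685 (22.5%) lay over 1 kb from any start site, 2662 of them in gene bodies and 2023 between genes, with a median signal value of 4.93 against 20.7 for all. Over 5 kb from any start site there were 2296 (11.04%), 856 in gene bodies and 1440 between genes. The widest domains in that class were 6959 bp on chromosome 13 (21166694 to 21173652, 5.79 kb from Trim27), and 6365 bp on chromosome 2 (115854780 to 115861144), downstream of Meis2 and 203 kb from its start sites. Next came 5875 bp within the gene body of Srcin1, 5563 bp within Bcor on chromosome X, and 4195 bp within the noncoding gene Lncppara on chromosome 15. All 5 had peaks in both replicates. In the replicates' own lists the counts were 7486 and 9101 over 1 kb, and 3152 and 3809 over 5 kb. Against start sites of protein-coding genes only, 4340 replicated peaks lay over 5 kb away.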

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

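Width without merging was an alternative set in advance, but its use as a test of joined peaks was chosen after the result was seen. The tests of CpG content, of signal value and of lineage for the wide domains were also chosen after the result was seen, as was the split of the other lineages by list. The other tests in this part were set before their results were seen.

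Outside the comparisons, 11 replicated peaks lay on unplaced or unlocalized scaffolds, where the annotation used here defines no promoter, and their median signal value was 5.60. The highest of them, on a scaffold assigned to chromosome 4, had a signal value of 33.7.

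Wide domains at the neural progenitor, dorsoventral, spinal neuron, pan-neuronal and Hox lists were weighed against 3 technical explanations. Neighbouring peaks joined by merging, as the whole cause, were argued against in 4 of the 4 lists other than spinal, which stayed wider without merging (log2 differences of 0.37 for dorsoventral factors, 0.65 for pan-neuronal, 1.40 for Hox and 1.52 for neural progenitor genes), although the dorsoventral difference was 0.83 with merging. In the spinal list joined peaks may account for the width, since its log2 difference without merging was -0.046, against 1.20 with it; more bp were covered within 5 kb of the start site in 5 of the 5 lists, but several neighbouring peaks would give this as well, so it decides nothing. CpG content within 500 bp of the start sites was also argued against as the whole cause. After matching on it 5 of the 5 lists stayed wider in merged width, by log2 differences of 0.93 to 1.74. How far CpG-rich sequence extends beyond that was not matched and stays untested. Higher signal was argued against by a lower median signal for dorsoventral (15.7), spinal (13.3) and pan-neuronal genes (18.3) than the 33.0 of other promoter domains. Hox (24.8) and neural progenitor genes (35.1) passed no test of signal. After matching on signal value 5 of the 5 lists stayed wider, by 1.19 to 1.82. All but the progenitor list were then set against narrower domains, so this decides nothing for them. For neural progenitor genes 1.72 was left. Domains of the progenitor, dorsoventral and spinal lists had a median of 4751 bp (91 domains) against 1702 bp (37 domains) for the somite, heart and limb and endoderm lists, a log2 difference of 1.48, but the widths of these lists were known when they were picked, so the comparison decides nothing and the lineage of the tissue stays open as untested.

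Marked promoters at genes of other lineages numbered 57 of the 123 members of the somite, heart and limb, endoderm, blood and endothelial lists (46.3%). CpG-rich promoters marked whatever the lineage may account for this pooled count. Random lists matched on CpG decile gave a mean of 47.4%, with 95% of them between 42.3% and 52.8%. The count joins lists on both sides of their matched means, so it does not show this for each lineage. Endoderm (28% against 44.1%) and heart and limb members (50% against 61.65%) lay below. Somite (69.0% against 57.7%), endothelial (66.7% against 60.8%) and blood members (16.0% against 14.9%) lay above. Isl1 and Ptf1a, counted here, also stand on other lists. Cells of other types in the dissected tissue would add marks at CpG-poor start sites, and 21 of 86 such members were marked (24.4%) against 25.9% in matched lists (permutation p = 0.822). A share at or below the matched mean had been set in advance as counting against such cells. So small a difference decides neither way. By list, none of 10 heart and limb and 1 of 19 endoderm members were marked, fewer than matched genes (adjusted permutation p = 0.0240 for each), while somite (8 of 17 against 29.7%, 0.206), endothelial (8 of 16 against 41.8%, 0.618) and blood members (4 of 24 against 11.5%, 0.618) were not below. Mesodermal, vascular or blood cells therefore stay open as a source, and the abundant globin genes Hba-a1, Hba-x, Hbb-y and Hbb-bh1 had no peak, although some globin genes have near-identical copies.

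CpG-rich promoters without a peak were rare, with 31 of the 6581 genes in the upper 3 CpG deciles marked in none of the replicated and single-replicate lists. Near-identical copies elsewhere in the genome, whose reads have no single place, are a candidate explanation. In 80.6% of these genes (25 of 31) over 50% of the 32-mers within 500 bp of the outermost start site occurred more than once on the chromosomes, against 0 of 300 random marked genes of the same deciles. In genes with several start sites, that site need not be the one whose CpG ratio set the decile. The 25 include the histone genes Hist1h2ao, Hist1h2ap, Hist1h4m and Hist1h4n and the pair Entpd4 and Entpd4b, so a missing peak there does not show a missing mark. The other 6 (Asmt, Esx1, Fkbp6, Gm21738, Hsf5 and Yy2) did not pass that limit of 50%. Copies by this measure are therefore not a candidate for them, and no other explanation was tested.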

How the results depend on the processing

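Widths matched on CpG or signal and start sites of all GENCODE transcripts were added after the data were seen. The endoderm and liver list has no width value with gaps of 3 kb merged, in the pooled list or with each gene counted once, since it then had fewer than the 8 domains or genes needed; every other alternative set in advance was run. Depth is unknown, so its effect on the lists could not be computed. Of 210 alternatives for list coverage 179 kept direction and side of the threshold, as did 111 of 141 for domain width; where a call changed, the cause was not tested unless the setting itself removes or matches the quantity named.

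Overlap of replicate 1 with 2, and of 2 with 1, was 71.9% and 65.6% with a reciprocal overlap of 50%, 99.4% and 91.8% in the stronger 50% of each list, 91.4% and 97.3% at a -log10 q of at least 5, and 89.7% and 83.8% after merging across 1 kb. Spearman's rho was 0.966 with reciprocal overlap. The share at promoters was 74.2% with 2.5 kb windows, 62.0% in the pooled list, 74.0% at a -log10 q of at least 5, 94.7% in the stronger 50%, 72.4% with all GENCODE transcripts, and 56.0% to 59.3% in single replicates' lists. Marked genes were 63.3% with 0.5 kb windows, 64.7% with 2.5 kb, 64.2% in the pooled list, 63.2% at a -log10 q of at least 5, 49.3% in the stronger 50%, 64.8% with all transcripts and 64.2% to 64.4% in single replicates' lists. Peaks over 1 kb from any start site numbered 7486 to 9101 in single replicates' lists; those over 5 kb numbered 3152 to 3809 there, and 4340 against protein-coding start sites only.

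In the stronger 50% of peaks, coverage turned below other genes for dorsoventral (36.7%), spinal (26.3%), synapse (20%), forebrain (7.14%), somite (20.7%), endothelial (12.5%), patterning (48.6%) and imprinted genes (47.6%). The pan-neuronal (60%) and neural crest (54.2%) calls were lost there, and heart and limb (10%) and pluripotency (5%) passed as lower. The forebrain list passed as higher in the pooled list (89.3%) and ranged from 82.1% to 89.3% in single replicates' lists. The somite list, not called in the replicated list, lay just below other genes at a -log10 q of at least 5 (62.1%) and ranged from 62.1% to 69.0% in single replicates' lists, and the endothelial list did so at that limit (62.5%) and against genes without receptor families (66.7%). Matching on CpG leaves the share as it is and changes what it is set against. It ended the calls of the synapse (92.0%), endoderm (28%) and imprinted (90.5%) lists. The neural progenitor, spinal, cell cycle and housekeeping (100% each), dorsoventral (96.7%), neural crest (91.7%) and patterning (97.3%) calls were lost too, but there full marking could not pass either (adjusted p of 0.0509 to 0.962 with every member marked). The matched genes of these lists were marked in 89.9% to 97.4% of cases, nearer to the lists than the 63.8% of all genes. Matching also turned the uncalled forebrain (82.1%) and glial (60%) lists and the blood list (16.0%) to the other side of the matched mean.

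Log2 differences in width without merging were -0.046 for spinal, -0.29 for somite and -0.26 for pluripotency genes, all of the other sign, 0.016 for synapse genes, whose call was lost, and -0.80 for forebrain, -0.51 for heart and limb and -1.17 for endothelial genes, which passed as narrower. With gaps of 3 kb merged they were 0.27 for forebrain and 0.80 for heart and limb genes, both turned, 0.93 for pluripotency genes, now past the threshold, and 0.38 for synapse, 0.46 for Hox and -0.44 for glial genes, calls that were lost. With each gene counted once the Hox difference rose from 1.32 to 4.804, still called. In single replicates' lists forebrain genes were at 0.0032 to 0.088 and glial genes at -0.40 to -0.32. With each gene counted once the synapse (0.33), glial (-0.47) and somite (0.34) calls were lost. Matching on CpG gave 0.0083 for forebrain and 0.24 for endothelial genes, both turned, and -0.38 for glial genes, no longer called. Matching on signal value turned forebrain (0.83), heart and limb (0.49) and endothelial genes (0.70), brought pluripotency genes past the threshold (0.70), and ended the glial (-0.16), endoderm (-0.18) and housekeeping (0.22) calls.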

Other observations

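The gene families, the split of Hox genes by paralog group and the tests of CpG-poor neuronal genes, of signal value and of list members marked in 1 replicate only were chosen after the data were seen; the test of RefSeq start sites was set before its result was seen.

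Families of developmental genes varied in how many members were marked, and no enrichment of families was tested. All 12 LIM homeobox genes, 6 of 6 Irx genes and 5 of 5 Zic genes were marked, in each replicate too, with median domain widths of 4250, 6744 and 11447 bp. Neighbours can share a domain, as Zic1 and Zic4 did (14.0 kb), so members of a family are not always separate domains. Of 19 Sox genes 18 were marked (median 4716 bp) and of 19 Wnt genes 17 (2378 bp). The marked shares were lower among Fox genes (36 of 44, median 2576 bp), Pax genes (7 of 9, 6587 bp), Fgf genes (16 of 22, 2500 bp), Pou genes (10 of 16, 4606 bp) and Tbx genes (8 of 13, 2187 bp). Cytosolic ribosomal protein genes were marked in 76 of 79 cases with a median width of 2374 bp and a median signal value of 51.2. In contrast 6 of 53 keratin genes, 1 of 331 vomeronasal receptor genes, and none of 57 keratin-associated protein and 42 beta-defensin genes were marked. Median CpG ratios of these families were 0.32, 0.12, 0.17 and 0.11, against 0.63 (Tbx) to 0.82 (Irx) in the developmental ones. Family and CpG content are therefore not separated here. Clustered protocadherin genes, with a median ratio of 0.56, were marked in 14 of 57 cases.

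Within the Hox list, the 6 genes of paralog groups 12 and 13, the posterior end of the clusters, had signal values of 4.38 to 10.3 and domains of 590 to 2972 bp. The 33 genes of groups 1 to 11 had signal values of 16.5 to 64.1 and domains of 2099 to 88301 bp, and neighbouring genes share these values. Hoxb13 (650 bp, with 985 and 700 bp in the replicates' lists) and Hoxd12 (590 bp, with 1050 and 1029 bp) had the narrowest domains of the replicated list and Hoxd12 the lowest signal value, 4.38. No test was made, since most genes of groups 1 to 11 share a domain with a neighbour.

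Marking followed CpG content in steps. In the lowest decile of CpG observed over expected 0.683% of genes were marked, in the 4th decile 45.3%, in the 5th 87.7% and in the highest 99.5%. A hypothesis was that neuronal genes carry the mark at CpG-poor start sites. Of 25 pan-neuronal and synapse genes in the lower 5 deciles, 23 were marked (92.0%), in both replicates, against 50% of random genes of the same deciles (permutation p = 2.00e-04, the smallest the 10000 lists can give). Both lists were picked after their marked shares were known, so that lineage may add to CpG content at these promoters remains a hypothesis. Nhlh1 (4916 bp), Nhlh2 (4557 bp), Stmn2 (4547 bp) and Myt1 (6734 bp) are examples, the first 2 with CpG ratios of 0.0700 and 0.212.

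Wide domains were not always high, and the hypothesis that developmental factor lists have a lower highest signal than other marked promoters was tested on the dorsoventral, spinal neuron and forebrain lists, of which the last did not pass the width test (log2 difference -0.053). In 3 of the 3 lists the median was lower than the 33.0 of other promoter domains: 15.7 for dorsoventral factors (adjusted permutation p = 3.60e-04), 13.3 for spinal neuron factors (1.20e-04) and 8.90 for forebrain factors (1.20e-04). Neural progenitor genes (35.1, adjusted permutation p = 0.690) and Hox genes (24.8, adjusted permutation p = 0.148) did not pass the test, and housekeeping genes were higher (46.2, adjusted permutation p = 0.00344). A lower median passed the test in 14 of the 18 lists, the endoderm (5.24), heart and limb (11.2) and endothelial (11.8) lists among them, so a low signal was not particular to developmental factors.

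Peaks over 5 kb from any GENCODE start site may in part be start sites of transcripts that the annotation lacks. Of 2296 such peaks 291 (12.7%) were within 1 kb of a RefSeq transcript start, against a mean of 1.23% and a maximum of 2.10% for random placements that kept the distance to GENCODE start sites. These 291 had a median signal value of 7.35, against 5.58 for the other 2005.

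Of 528 members of the fixed lists 13 were marked in 1 replicate only (2.46%), against 1.38% of other genes (two-sided Fisher's exact p = 0.0570). The 8 in replicate 1 were Aldh1l1, Arx, Myf5, Nkx2-1, Otx2, Pdx1, Six6 and Tnnt1, and the 5 in replicate 2 were Cd68, Dbx2, Fezf2, Phox2b and Tdgf1, with a median signal value of 4.01.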
